A study of Homo sapiens with 9 samples.

How the data were processed

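A673 is an established Ewing sarcoma cell line that carries the EWSR1-FLI1 fusion gene. The series holds 9 samples of A673 cells expressing Cas9. Per the labels' protocols, guide RNAs against RUVBL1 (sgRUVBL1) or control guides (sgCtrl) were delivered by lentivirus and cells were selected in puromycin at 1 µg/ml for 4 days. The labels list 4 RNA-seq samples, 2 per group, and 5 samples of MYC chromatin immunoprecipitation sequencing and its input. The MYC binding data are not analysed here, so the comparison of MYC occupancy between the groups is left out.

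The RNA-seq values are raw read counts per gene symbol in 4 columns, deposited as a single merged count table by the authors. Per the labels' protocols, total RNA was extracted with a column kit and the libraries were made with a directional mRNA kit. Per the file headers, reads were aligned with STAR, sorted by coordinate and marked for duplicates, and the summary rows of the table are those of HTSeq. STAR 2.6.0a, SAMtools 1.10, Picard, edgeR and the genome build GRCh38 are listed per the submitters' processing notes, without their role. The gene annotation, the HTSeq version, the strand setting and whether marked duplicates were counted are not given in the sources used here. Counts of marked duplicates would make a count less independent than its size says. Without a stated strand setting, reads of overlapping genes on opposite strands may have been shared or discarded.

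The columns are named Luc, R2, R3 and by a further reporter name, and that library is called the other control here. Luc and the other control were taken as the 2 sgCtrl libraries, since both names are those of reporter genes used as control targets, and R2 and R3 as the 2 sgRUVBL1 libraries. This mapping rests on the names and not on the values, although RUVBL1 counts had been printed before it was written down. The names do not tell which library is sample 1 or 2 of its group, nor whether R2 and R3 received different guides. Nothing in the labels says that the 2 samples of a group were separate cultures, so the p-values measure the spread between these libraries, which may be technical. The libraries of each group differed from each other by more than counting noise (chi-square per degree of freedom 3.08 between the 2 controls and 4.66 for R2 against R3), so none was treated as a copy.

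Rows that name no gene were left out of library sizes and tests. Reads in no annotated gene made up 16.6%, 13.5%, 18.0% and 17.1% of all rows in Luc, the other control, R2 and R3. Reads matching more than 1 gene made up 2.56%, 2.69%, 2.49% and 2.52%, and multi-mapped reads 2.05%, 2.05%, 2.59% and 2.72%, in the same order. The remaining gene counts came to 16876151, 19839594, 17958348 and 16749065. At these depths a count of 0 allows up to 0.178, 0.151, 0.167 and 0.179 CPM, counts scaled to the total gene counts of the library. The 95% exact binomial intervals given for RUVBL1 cover counting error only, since reads carry no molecular identifiers.

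Genes were tested with edgeR 4.0.16 in R 4.3.3. Of 19845 genes in the table, 13275 passed filterByExpr with its minimum count of 10. Libraries were scaled by TMM, and sgRUVBL1 was compared with sgCtrl by the quasi-likelihood F-test at default settings, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene's standard error (SE) is its absolute log2 fold change divided by the square root of F. With 2 residual degrees of freedom per gene, the test draws mostly on the spread shared across genes, with 32.7 prior degrees of freedom and a biological coefficient of variation of 0.0499. Group levels are TMM-scaled CPM as mean ± SD with n = 2. No spike-in was named in the labels, so changes are relative to the trimmed bulk of genes that TMM sets level, and a shift shared by all genes would not show.

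28 gene lists were fixed before the data were examined, from textbook knowledge of RUVBL1, MYC, Ewing sarcoma and stress pathways, with 4 lists of markers of other cell types or states. Each list was tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists. Camera compares a list with the other genes. The same test with an estimated correlation and the fry test were alternatives.

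Named genes follow a rule fixed at the same time. It takes RUVBL1, RUVBL2, MYC, MAX, EWSR1, FLI1, NR0B1, NKX2-2 and CDKN1A in any case. It adds the 6 largest rises and the 6 largest falls among genes past the threshold whose groups do not overlap and whose mean is at least 5 CPM. From each list it takes up to 3 members past the threshold with the smallest p, or the member with the smallest p where none passed. This gave 98 genes. Other genes are said to have been chosen after their values were seen. Some results by this rule or found later are not reported here. Coordinates come from a RefSeq gene table of GRCh38 and are 1-based. 19209 of the 19845 symbols (96.8%) were located by symbol or unique synonym.

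The steps were tested on simulated counts with the means and library sizes of these 4 libraries, with 200 changed genes among 13135 tested. Changed genes were taken from those with a mean count of at least 100. Every gene had the same spread and was drawn independently of the others. The recovery therefore does not cover genes of lower count or larger spread, nor data in which a large part of the genes change. The test recovered 44% of genes changed 1.25-fold, 92% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold, and 6 of 174 calls were unchanged genes. Alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, robust empirical Bayes, stricter thresholds and each library left out in turn.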

Results

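The transcriptome of A673 Ewing sarcoma cells was measured by RNA-seq after Cas9 editing with guides against RUVBL1 (sgRUVBL1) or control guides (sgCtrl), with 2 libraries per group. RUVBL1 encodes an AAA+ ATPase that works with its partner RUVBL2 in the TIP60, INO80 and SRCAP chromatin complexes and in the R2TP chaperone. The series pairs this knockout with MYC chromatin immunoprecipitation, and the comparison addresses which transcripts change when RUVBL1 is targeted. Total gene counts ranged from 16749065 to 19839594 per library. Log2 CPM correlated across genes at 0.994 within both groups, and the first principal component, which held 86.7% of the variance, separated sgCtrl from sgRUVBL1.

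RUVBL1 mRNA was lower in both sgRUVBL1 libraries than in both controls. The gene lies on chromosome 3 from 128064785 to 128153914 (GRCh38). Its counts were 3426 and 4138 in the control library Luc and the other control library, and 958 and 1922 in the sgRUVBL1 libraries R2 and R3. Scaled to the total gene counts, RUVBL1 stood at 203 CPM (95% interval 196 to 210) in Luc and 209 CPM (202 to 215) in the other control, against 53.3 CPM (50.02 to 56.8) in R2 and 115 CPM (110 to 120.0) in R3. The TMM-scaled level fell from 213 ± 4.64 to 81.0 ± 41.4 CPM (SD, n = 2), a log2 fold change of -1.40 ± 0.14 (SE, edgeR adjusted p = 2.29e-10). The 2 sgRUVBL1 libraries differed in how much RUVBL1 mRNA was left, and the log2 fold change was -2.05 without R3 and -0.96 without R2. With robust empirical Bayes, which lets a gene keep its own spread, the adjusted p was 0.129. The annotated span overlaps EEFSEC and SEC61A1, so a share of reads may be uncertain. RUVBL2, the partner ATPase, was at 207 ± 10.99 and 224 ± 10.6 CPM (log2 fold change 0.11 ± 0.06, adjusted p = 0.131; 0.05 without Luc and 0.06 without R3). It passed the threshold with total count scaling (adjusted p = 0.00351), with a mean CPM filter of 10 (0.0210) and without R2 (0.0226).

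**Figure D1:**
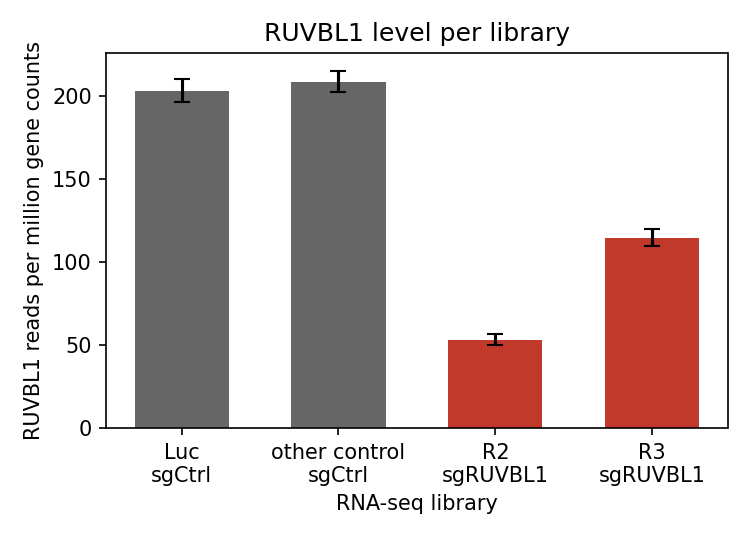
RUVBL1 level in CPM of total gene counts (y axis) in each RNA-seq library (x axis), with 95% exact binomial intervals as error bars; grey bars are sgCtrl and red bars sgRUVBL1. R2 at 53.3 and R3 at 115 lie below both control libraries at 203 and 209.

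Changes reached a large part of the transcriptome. Of 13275 tested genes, 7893 (59.5%) passed the threshold, 3936 higher and 3957 lower in sgRUVBL1. Changes of at least 2-fold were more often rises, with 1046 genes higher and 297 lower. The largest rises were UGT3A1 on chromosome 5, a UDP-glycosyltransferase gene (0.586 ± 0.134 to 13.0 ± 1.97 CPM, log2 fold change 4.44 ± 0.26), and HS3ST2 on chromosome 16, a heparan sulfate sulfotransferase gene (log2 fold change 3.56 ± 0.22). NATD1, CMYA5, ABTB1 and VWA5A rose by 2.93, 2.84, 2.73 and 2.62 on the log2 scale. UGT3A1 has the paralog UGT3A2, with which it can share reads. UGT3A2, looked up after its values were seen, stood at 632 CPM in sgCtrl and 628 CPM in sgRUVBL1. Its log2 fold change was -0.01 ± 0.06 (edgeR adjusted p = 0.916), which argues against a rise of the paralog as the source. Among the 6 largest falls, 4 were interferon-induced antiviral genes. These were IFIT1 (39.4 ± 1.92 to 6.55 ± 1.88 CPM, log2 fold change -2.58 ± 0.13), IFIT2 (-2.18 ± 0.10), IFIT3 (-2.09 ± 0.11) and OASL (-2.09 ± 0.16). The 3 IFIT genes lie together on chromosome 10 and overlap the annotated span of LIPA. S100A16, a calcium-binding protein gene, and ANKRD1, a muscle ankyrin repeat gene, each fell by 2.08. All of these had an edgeR adjusted p of 3.61e-10 or less. The groups did not overlap in 81.1% of tested genes, against 33.3% by chance with 2 libraries per group. With scaling by total count alone, 63.2% of calls were higher against 49.9% with TMM, and the median of all genes moved by 0.10 on the log2 scale. Of the 7893 calls, 6040 were also made in the same direction by DESeq2.

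**Figure D2:**
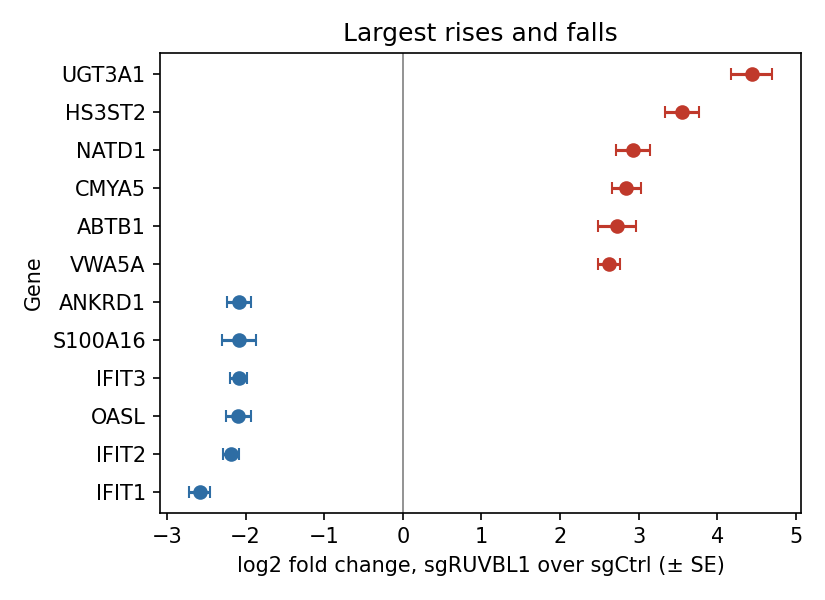
Log2 fold change of sgRUVBL1 over sgCtrl (x axis) for the 6 largest rises and 6 largest falls (y axis), with points at the edgeR estimate and bars of 1 standard error. The rises run from 2.62 for VWA5A to 4.44 for UGT3A1 and the falls from -2.08 for ANKRD1 to -2.58 for IFIT1.

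MYC target genes were lower in sgRUVBL1 while MYC mRNA itself was higher. Of 64 tested MYC targets, 49 fell, 1 rose and 14 did not pass the test, and the median log2 fold change was -0.33, or -20.5% on the linear scale. HSPD1, the mitochondrial chaperonin gene, fell by 0.81 ± 0.06, NPM1, the gene of a nucleolar phosphoprotein, by 0.73 ± 0.06, and RABEPK by 1.01 ± 0.09 on the log2 scale. Adjusted over the list alone, 49 fell and 2 rose. Camera placed the list below the other genes (adjusted p = 1.26e-07), but with an estimated correlation the adjusted p was 0.565. MYC rose from 434 ± 1.70 to 520 ± 17.9 CPM (log2 fold change 0.26 ± 0.06, adjusted p = 0.000275). Its dimerisation partner MAX fell (-0.26 ± 0.08, adjusted p = 0.00403), a call lost without the control other than Luc (adjusted p = 0.0870) and with total count scaling (0.0796). Of 12 tested MYC family and partner genes, 7 rose and 2 fell, and the list was not past the camera threshold (adjusted p = 0.224). MLXIPL, a glucose-responsive transcription factor gene, rose by 2.24 ± 0.19 from 2.79 CPM, MYCN by 1.97 ± 0.23 from 2.36 CPM and MXD4, a MYC antagonist gene, by 1.03 ± 0.14. MYCN overlaps the antisense gene MYCNOS.

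Genes tied to the EWSR1-FLI1 fusion moved in both directions. EWSR1 fell (-0.62 ± 0.06, adjusted p = 2.46e-10) and FLI1 was at 133 ± 1.74 and 122 ± 2.32 CPM (-0.13 ± 0.06, adjusted p = 0.0723; 0.0294 without R2). Gene counts do not separate fusion reads from those of the unfused EWSR1 and FLI1 alleles. Of 28 genes that the fusion is known to activate, 11 rose, 5 fell and 12 did not pass, with a median of 0.04 (camera adjusted p = 0.337). That median was 0.027 without the control other than Luc and 0.019 without R2. NKX2-2, a homeodomain factor gene, rose from 29.2 ± 1.90 to 90.2 ± 10.3 CPM (1.62 ± 0.09), and CCK, a neuropeptide gene, and FCGRT, the neonatal Fc receptor gene, rose by 1.20 ± 0.07 and 1.07 ± 0.07. NR0B1, an orphan nuclear receptor gene, fell (-0.39 ± 0.06, adjusted p = 2.26e-06). Of 25 tested genes that the fusion is known to repress, 16 fell and 3 rose, with a median of -0.45 (camera adjusted p = 0.00362; adjusted p = 0.565 with an estimated correlation). CTGF and CYR61, matricellular protein genes, fell by 1.64 ± 0.07 and 1.26 ± 0.07, and COL1A2, a collagen gene, by 1.17 ± 0.07. Adjusted over the list alone, 16 fell and 4 rose.

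The complexes that hold RUVBL1 showed changes of single subunits in both directions and no list past the camera threshold. Of all tested genes, 59.5% passed the edgeR threshold, 3936 higher and 3957 lower, so calls in both directions are not particular to these complexes. In the TIP60 and EP400 complex, 5 of 17 genes rose and 7 fell (median -0.07, adjusted p = 0.766; -0.10 without R2 and -0.043 without R3). MBTD1, EPC1 and BRD8 rose by 0.76 ± 0.08, 0.49 ± 0.06 and 0.47 ± 0.07. In INO80 and SRCAP, 4 of 14 rose and 5 fell, and the median (0.06) and the mean (-0.03) had opposite signs (adjusted p = 0.851). UCHL5 (-0.51 ± 0.07) and ACTR8 (-0.51 ± 0.10) fell and ZNHIT1 rose (0.53 ± 0.09). Among the R2TP chaperone and its kinase and small nucleolar ribonucleoprotein clients, 5 of 22 rose and 6 fell (median -0.07, adjusted p = 0.630; -0.12 without the control other than Luc). PDRG1, an R2TP-associated subunit gene, rose by 0.88 ± 0.08 and TELO2, of the TTT kinase cochaperone, by 0.35 ± 0.07, while GAR1, an H/ACA ribonucleoprotein gene, fell by 0.59 ± 0.07.

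Genes for ribosomes and nucleotides were lower. Of 79 cytosolic ribosomal protein genes, 70 fell, 0 rose and 9 did not pass (72 fell adjusted over the list alone), with a median log2 fold change of -0.37 (camera adjusted p = 3.06e-10; adjusted p = 0.565 with an estimated correlation). RPLP0, RPS12 and RPL10 fell by 0.68 ± 0.06, 0.66 ± 0.07 and 0.61 ± 0.06. These genes have processed pseudogenes that can take or lose reads. Multi-mapped reads made up 2.05% of rows in both controls and 2.59% and 2.72% in R2 and R3. Of 19 nucleotide synthesis genes, 18 fell and 0 rose, with a median of -0.55 (camera adjusted p = 5.07e-05; adjusted p = 0.565 with an estimated correlation). IMPDH2, of guanine nucleotide synthesis, fell by 0.81 ± 0.07, CTPS1, of CTP synthesis, by 0.78 ± 0.07 and PAICS, of purine synthesis, by 0.66 ± 0.06. Of 23 RNA polymerase I and III genes, 13 fell and 4 rose (median -0.22, camera adjusted p = 0.0379; adjusted p = 0.565 with an estimated correlation, 0.0517 with a CPM of at least 1 in 2 libraries and 0.0546 with total count scaling). POLR3G fell by 1.48 ± 0.13 and CD3EAP, a polymerase I subunit gene that overlaps ERCC1, by 0.95 ± 0.08, while RRN3, a polymerase I initiation factor gene, rose by 0.81 ± 0.07.

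Mitosis genes were lower. Of 28 mitosis genes, 22 fell and 2 rose, with a median of -0.42 (camera adjusted p = 0.000289; adjusted p = 0.565 with an estimated correlation). CCNB1 and CDC20, regulators of mitotic entry and exit, fell by 0.78 ± 0.06 and 0.74 ± 0.06, and DLGAP5, a spindle protein gene, by 0.73 ± 0.07. Of 35 DNA replication genes, 19 fell and 6 rose (7 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 0.0379; adjusted p = 0.565 with an estimated correlation). The median lay at percentile 7.66 of 10000 random lists matched on expression level, inside their central 95% (-0.22 to 0.083). The camera call was lost without the control other than Luc (adjusted p = 0.0520), with a CPM of at least 1 in 2 libraries (0.0533) and with total count scaling (0.0772). RRM2, the ribonucleotide reductase subunit gene, fell from 463 ± 13.0 to 199 ± 40.9 CPM (-1.22 ± 0.08), and TYMS, which overlaps ENOSF1, and CDC45 fell by 0.75 ± 0.06 and 0.76 ± 0.08. Replication-dependent histone genes went the other way. Of 13 tested, 12 rose and 1 fell, with a median of 0.94 (camera adjusted p = 0.000124; adjusted p = 0.565 with an estimated correlation). HIST1H2BD, HIST2H2BE and HIST1H2AG rose by 1.35 ± 0.09, 1.55 ± 0.12 and 2.17 ± 0.18. As a class, these transcripts mostly lack a poly(A) tail and come from near-identical gene copies, so their counts are uncertain. Whether the transcripts counted here had a tail was not measured.

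Stress pathways were mixed. Of 22 tested p53 targets, 8 rose and 5 fell (median 0.09, camera adjusted p = 0.449), and the median was 0.029 without the control other than Luc. CDKN1A, the p21 cell cycle inhibitor gene, rose by 0.58 ± 0.07 and FAS, the death receptor gene, by 1.09 ± 0.08, and AEN, an apoptosis nuclease gene, fell by 0.58 ± 0.07. FAS overlaps ACTA2. Of 21 genes of the integrated stress response, 7 rose and 9 fell (median -0.11, adjusted p = 0.365). DDIT3, the CHOP transcription factor gene, rose by 1.25 ± 0.08, whereas the amino acid synthesis genes PSAT1 and ASNS fell by 1.39 ± 0.08 and 0.91 ± 0.09. Of 18 endoplasmic reticulum chaperone genes, 7 rose and 3 fell (median 0.10, adjusted p = 0.224), including rises of DNAJB9 (0.72 ± 0.12) and SEL1L (0.39 ± 0.07) and a fall of XBP1 (-0.57 ± 0.07). Of 15 cytosolic heat shock protein genes, 9 fell and 3 rose (median -0.18, adjusted p = 0.224). HSPA8, HSP90AB1 and FKBP4 fell by 0.68 ± 0.06, 0.67 ± 0.06 and 0.62 ± 0.06.

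Of 25 tested interferon-stimulated genes, 15 fell and 6 rose, with a median of -0.65 and members from -2.58 to 1.45. The list was not past the camera threshold (adjusted p = 0.0785, or 0.565 with an estimated correlation). It passed camera with no filter (adjusted p = 0.0114) and with total count scaling (0.0187), but not with the other scalings or the stricter CPM filter. Its camera call depended on which library was left out. The list median was -0.54 without Luc, -0.76 without the other control, -0.79 without R2 and -0.58 without R3. Of 11 tested NF-kB targets and cytokines, 5 rose and 1 fell (median 0.11, adjusted p = 0.159), and the median was 0.51 without the control other than Luc and 0.18 without R2. BIRC3, an inhibitor of apoptosis gene, rose from 0.534 ± 0.0604 to 3.54 ± 0.191 CPM (2.70 ± 0.35), and ICAM1 and CCL20 rose by 1.81 ± 0.29 and 2.56 ± 0.47 from 1.20 and 0.284 CPM. Members with more counts, chosen after their values were seen, rose less or did not rise. CXCL8 rose by 0.92 ± 0.17 from 5.66 CPM and NFKB2 by 0.51 ± 0.11 from 17.1 CPM. RELB did not pass (-0.02 ± 0.16 from 9.55 CPM, edgeR adjusted p = 0.907). NFKBIA, the 1 that fell, changed by -0.26 ± 0.11 from 25.6 CPM, and TNFAIP3 did not pass (0.11 ± 0.10 from 28.2 CPM, edgeR adjusted p = 0.339).

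Lysosome and autophagy genes were higher. Of 24 tested, 17 rose and 0 fell, with a median of 0.38 (camera adjusted p = 0.000531; adjusted p = 0.565 with an estimated correlation). NEU1, the lysosomal sialidase gene, rose by 1.23 ± 0.09, GABARAPL1, of the autophagosome, by 0.81 ± 0.07 and TPP1, a lysosomal peptidase gene, by 0.66 ± 0.07. Of 22 cholesterol synthesis genes, 10 rose and 3 fell (median 0.15, adjusted p = 0.259; 0.093 without the control other than Luc), and IDI1 and SREBF2 rose by 0.55 ± 0.07 and 0.48 ± 0.06. Of 16 tested hypoxia response genes, 4 rose and 6 fell (median -0.13, adjusted p = 0.766). NDRG1 rose by 1.12 ± 0.10, and LOXL2 and PFKFB3 fell by 1.06 ± 0.11 and 0.51 ± 0.06.

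Immediate early genes, which respond to growth factors within minutes, were lower. Of 15 tested, 11 fell and 2 rose, with a median of -0.45 (camera adjusted p = 0.00269; adjusted p = 0.565 with an estimated correlation), and the transcription factor genes FOS, FOSB and EGR1 fell by 1.46 ± 0.07, 1.29 ± 0.09 and 1.01 ± 0.07. NGFR, the low-affinity nerve growth factor receptor gene, rose from 84.7 ± 0.508 to 506 ± 115 CPM (2.58 ± 0.09, adjusted p = 8.36e-22), while the intermediate filament genes NES and NEFM fell by 1.41 ± 0.08 and 1.27 ± 0.09. The 16 tested neural genes moved both ways, 5 higher and 6 lower, with a median of -0.01 and a mean of 0.08 (adjusted p = 0.823). That median was 0.13 without Luc, -0.16 without R3, and -0.015 without either of the other libraries. Of 13 mitochondrially encoded genes, 5 rose and 2 fell (median 0.02, adjusted p = 0.630). That median was 0.16 without Luc, -0.091 without the other control, 0.051 without R2 and 0.086 without R3. MT-ATP8 and MT-ND4L rose by 0.72 ± 0.12 and 0.34 ± 0.06. MT-ND1 rose by 0.23 ± 0.07 (0.41 without Luc), a call lost at 0.061 without the other control (adjusted p = 0.590) and in DESeq2 (0.337).

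**Figure D3:**
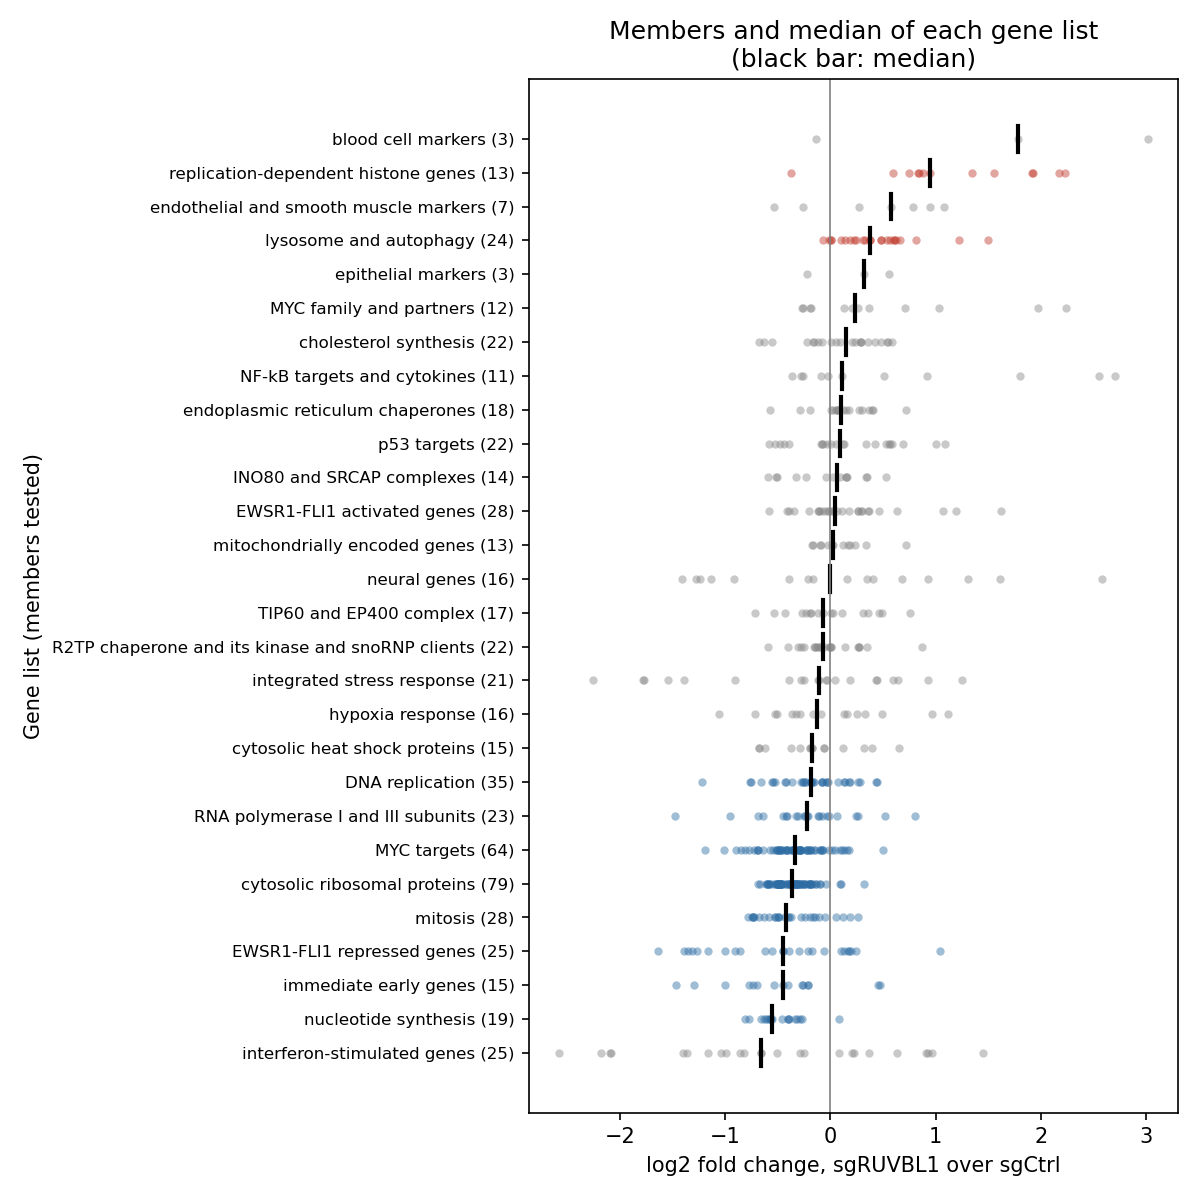
Log2 fold change of sgRUVBL1 over sgCtrl (x axis) of the tested members (points) and their median (black bar) for each of 28 gene lists (y axis, members tested in brackets). Blue and red lists passed camera's adjusted p of 0.05 at the preset correlation of 0.01, lower and higher, and medians run from -0.65 for interferon-stimulated genes to 1.78 for blood cell markers, which were not past it.

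Most markers of other cell types had too few counts to be tested, with 3 of 10 epithelial, 3 of 11 blood and 7 of 11 endothelial and smooth muscle markers left. Among the blood cell markers, CD14 and ITGAM rose by 3.02 ± 0.44 and 1.78 ± 0.25 to 2.34 and 7.31 CPM (list median 1.78, camera adjusted p = 0.259). CD68, the other tested blood marker, was added after its values were seen. It did not pass, at 8.54 CPM in sgCtrl and 7.73 CPM in sgRUVBL1 (-0.14 ± 0.17, edgeR adjusted p = 0.492). Of the 7 endothelial and smooth muscle markers, 3 rose and 1 fell (median 0.57, adjusted p = 0.337). ACTA2 and PECAM1 rose by 1.08 ± 0.08 and 0.95 ± 0.26, and TAGLN fell by 0.54 ± 0.08. Among the epithelial markers, KRT8 rose by 0.32 ± 0.07 and KRT18, which overlaps it, fell by 0.22 ± 0.06 (list median 0.32, adjusted p = 0.720). The KRT18 call was lost with total count scaling (adjusted p = 0.0727) and without the control other than Luc (0.0531). Counts adjusted over the list alone equalled those over all genes tested for 21 of the 28 lists and differed by at most 2 genes in the others.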

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

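The scaling test of the ribosomal protein and MYC target pattern and the S phase tests of the histone pattern were chosen after the results were seen. Chance alone puts both sgRUVBL1 libraries above both controls, or both below, each in 16.7% of such comparisons.

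Reads in no annotated gene and multi-mapped reads were more frequent in both sgRUVBL1 libraries than in both controls, and ambiguous reads were less frequent. Reads in no annotated gene averaged 15.05% of rows in sgCtrl and 17.5% in sgRUVBL1, and multi-mapped reads 2.05% and 2.66%, and ambiguous reads 2.62% and 2.51%.

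Cytosolic ribosomal protein genes and MYC targets were lower in sgRUVBL1. The choice among the 4 scalings used does not account for this, since the highest of the 8 medians, for 2 lists, was still -0.23. These scalings moved the median of all genes by at most 0.10 from TMM. None of them can show a shift shared by all genes. Expression level of the genes does not account for the whole of it, since both medians lay at percentile 0 of 10000 random lists matched on that level. Those lists also fell, with medians of -0.16 for the ribosomal protein genes and -0.094 for MYC targets, against -0.37 and -0.33, so a part of the fall is shared with genes of the same level. Reads moved to multi-mapped alignments cannot be told apart from a real fall for the ribosomal protein genes, because multi-mapped reads rose by 0.889 of the fall in ribosomal protein reads, both scaled to all rows of the library, and by 0.633 of the fall of both lists together. The knockout itself also stays open as an untested biological explanation.

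Replication-dependent histone genes were higher in sgRUVBL1 (median 0.94). More RNA without a poly(A) tail in the libraries may account for this, since the upper end of the 95% bootstrap interval for 7 histone genes with a poly(A) tail was 0.33, below the bound of 0.47 set from the histone median. H1F0 among those 7 rose by 0.99 ± 0.08. Any other rise limited to the replication-dependent genes would leave the 7 behind as well, so this test does not single out the library explanation. More cells in S phase as the whole of the rise is excluded only if S phase raises replication genes at least 50% as much as these histone genes. That condition was not tested. The upper end of the interval for the DNA replication median was -0.040, which is 0.026 above the median of random lists matched on expression level (-0.066) and below the same bound of 0.47. A smaller share of S phase in the rise cannot be told apart from none, because that upper end is above the matched median, and the list median of -0.18 lay at percentile 7.66 of those lists (central 95% -0.22 to 0.083). A separate fall of replication genes that hides more S phase was not tested. The 3 bounds for S phase, at 0, at the matched median and at 0.47, were all set after the list had been seen, the last 2 after the interval was known. The bound at 0 would exclude any share, if replication genes follow S phase. Whether the counted histone transcripts had a poly(A) tail was not measured, and a change in histone transcript processing in the knockout was not tested.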

How the results depend on the processing

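The total count and upper-quartile settings for gene lists and edgeR's legacy=FALSE setting were chosen after seeing the data. No paired analysis was possible because the columns carry no replicate numbers. The planned legacy=TRUE setting is edgeR's default here and gave no further value. A left-out library leaves a lone sample that is assumed to vary like the other group.

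The counts of genes higher and lower stayed within 1.5 times 3936 and 3957 under all scalings, filters and tools, with DESeq2 giving 2826 and 3244. They ranged from 3015 to 3968 and from 3160 to 4107 with a library left out, and 5119 of the 7893 calls were kept in all 4 of those fits. A 2-fold minimum gave 1046 higher and 297 lower, and a test against 1.5-fold 992 and 481, as stricter criteria must. RUVBL1 stayed lower throughout (-0.96 to -2.05 with a library left out), but robust empirical Bayes gave -1.40 with adjusted p = 0.129, where its prior degrees of freedom were 0.279 in place of 32.7. Its adjusted p was at most 0.0178 elsewhere. Of 1344 values of other named genes, 1334 kept direction and side of the threshold, 6 lost the call, 4 gained it and 0 turned.

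With an estimated correlation 0 of 28 lists passed, with medians that do not depend on it: MYC targets -0.33, EWSR1-FLI1 repressed -0.45, ribosomal proteins -0.37, RNA polymerases -0.22, nucleotide synthesis -0.55, DNA replication -0.18, mitosis -0.42, lysosome 0.38, immediate early genes -0.45 and histones 0.94. In the simulation the same test gave an adjusted p of 0.100 to a list of 60 independent genes lowered by 0.35 on the log2 scale. It can thus miss a change of that size with libraries of these depths. Estimated correlations of the 10 called lists ran from 0.0068 for EWSR1-FLI1 repressed genes to 0.73 for ribosomal proteins, against the preset 0.01. For EWSR1-FLI1 repressed genes the estimate lay below the preset value, which argues against correlated genes as the source of that lost call. For the other called lists, the simulation, without such correlation, cannot tell whether low power or correlated genes account for the loss. Fry, which does not compare a list with other genes, passed 19 lists, adding MYC family 0.23, EWSR1-FLI1 activated 0.041, p53 targets 0.088, chaperones of the endoplasmic reticulum 0.10, heat shock proteins -0.18, interferon-stimulated genes -0.65, NF-kB targets 0.11, blood markers 1.78 and endothelial markers 0.57. It turned the test direction of TIP60 and EP400 (-0.068) and hypoxia (-0.13), neither past the threshold.

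RNA polymerases lost the call at -0.21 with a CPM of at least 1 in 2 libraries and at -0.12 with total count, and DNA replication at -0.17 and -0.075. Interferon-stimulated genes gained it at -0.76 with no filter and -0.55 with total count. With a library left out, medians ranged from -0.20 to -0.17 for DNA replication and -0.79 to -0.54 for interferon-stimulated genes. Whether either of these lists passed depended on which library was left out. The median of neural genes changed sign (-0.16 to 0.13), and those of NF-kB targets (0.12 to 0.51) and p53 targets (0.029 to 0.11) moved over 1.5 times, none past the threshold. Test directions turned for INO80 and SRCAP (0.043 to 0.057) and mitochondrial genes (-0.091 to 0.16), never past the threshold. The cause was not tested except where stated. At these depths, 44% of simulated 1.25-fold changes were recovered, among genes of high count and with the same spread for every gene.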

Other observations

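The test of chromosome arm loss as the whole of the RUVBL1 fall, the choice of genes in this part and the idea of each hypothesis came after results were seen. Members of the interferon-stimulated list moved both ways. IFI27 (1.45 ± 0.31), STAT2 (0.97 ± 0.09), IRF9 (0.93 ± 0.30), IRF7 (0.91 ± 0.13) and OAS3 (0.36 ± 0.10) rose, IFI44 (-1.40 ± 0.10) and ISG15 (-0.86 ± 0.08) fell, and IFI6, RSAD2, PARP9 and BST2 did not pass the test.

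The sgRUVBL1 library with more RUVBL1 mRNA lay farther from the controls. R3, at 115 CPM of RUVBL1, had a first principal component score of 43.2, and R2, at 53.3 CPM, a score of 30.2, against -37.4 and -36.0 for the controls. RUVBL1 protein was not measured here.

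More genes were detected in sgRUVBL1, with 15942 and 16008 genes holding a count against 15274 and 15327. ALOX15B, FCRL1, GS1-259H13.2, MT1M and SPN had 0 counts in both controls and at least 10 counts in each sgRUVBL1 library, and 0 genes showed the reverse.

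YAP and TEAD target genes were lower. Of 22 tested, 13 fell and 1 rose (median -0.58), and MYOF, CTGF and ANKRD1 among them prompted the test. A candidate explanation is lower activity of YAP and TEAD. Leaving out the 5 members that had been seen or belong to another list, the other 17 had a median of -0.54, at percentile 0 of 10000 matched random lists (their median -0.029), with 9 lower, 1 higher and a 95% bootstrap interval from -0.71 to 0.05. AXL, F3, FJX1 and NT5E fell by 1.22, 0.90, 1.08 and 0.58, and GADD45A rose by 0.44. The random lists were matched on expression level only, not on how genes vary together. Any other cause of a fall in these genes would give the same result, so this test does not single out YAP and TEAD. Protein levels and localisation of YAP were not measured here.

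Loss of the chromosome 3 arm beyond RUVBL1 could lower RUVBL1 itself. The 252 tested genes beyond it had a median of -0.07, with a 95% bootstrap interval from -0.17 to -0.01, and the 471 before it a median of -0.06. As the whole of the fall of 1.40 this is excluded, and a loss in a small part of the cells cannot be told apart from no loss.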
